A study of Mus musculus with 8 samples.

How the data were processed

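Total RNA from the triceps of each mouse was hybridised to its own Affymetrix Mouse Gene 1.0 ST array, and the 8 arrays fall into 4 wild-type controls and 4 Nf1Prx1 mutants by their labels. No samples were left out of the main fits, and no measurement column per sample went unused. Per the labels, the authors made the series values by RMA in the Affymetrix Expression Console in log2 units per transcript cluster, and the versions are not given. The text of the series names a further Affymetrix tool for exon arrays, and which steps used it is not stated. The authors also deposited a table of 234873 probe sets below the cluster level, with group means and standard deviations, minima and maxima of normalized log2 intensity, and lists of 1797 higher and 863 lower probe sets. Per the file headers that table gives a p value per probe set that is not adjusted, a ratio of control over mutant, a signed fold change, and the F and T scores of the authors' test. The deposited lists hold probe sets with F above 20 and a fold of at least 1.50, and 91 probe sets past both limits, with group means up to 6.0, are in neither list. The p values of the deposited table match an F distribution with 8 residual degrees of freedom (largest gap 5.89e-06) and not with 6 (largest gap 0.0125), and its standard deviations and T values imply 5 arrays per group (4.99 to 5.01 over 125669 probe sets more than 0.2 apart). Its notes and the series state 4, so its arrays could not be matched to the 8 arrays used here, and its values are always named as the authors'.

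Of 35556 clusters, 21789 had 1 gene symbol in the platform annotation, 1621 had several and 12146 were not listed, of which 6617 were taken as control probe sets by their ID. Symbols were updated through the Entrez ID, which matched 21698 clusters and left 91 with the older name. Clusters with several symbols or none were left out, and for the 999 genes with several clusters the one with the highest mean stood for the gene, which gave 19938 genes. No filter on dim genes was used in the main fit. The annotation used here names no genome build, so no coordinates are given. The number of arrays limits the precision, as do transcripts of other tissues in some of them, and array weights estimated by limma ran from 0.265 to 4.42.

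Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated test) and p values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Before the data were examined, the tests, the alternatives, 37 gene lists with 713 members (652 measured) and the rule for named genes were fixed. The rule names Nf1, then the 12 largest changes in each direction among genes that pass with both groups fully apart, or, if none passes, the 10 smallest p in each direction given as not passing, and from each list up to 4 members with the smallest p, or 2 where none of the list passes. No gene passed in the main fit, so the last options applied. The lists were tested with camera at a preset correlation of 0.01, adjusted over the 37 lists. Camera with an estimated correlation and fry were the alternatives, and neither called any of the 37 lists. Nf1 was also tested by an exact permutation of its 8 values. The deposited probe set table was read with pandas 2.3.3 and scipy 1.17.1, its p values were adjusted here over all its probe sets, and figures were drawn with matplotlib 3.10.9. Genes expected in its higher list were taken from the share of listed genes among those whose number of probe sets lay within 20% of each member's.

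The sample titles number the replicates 1 to 4 in each group, and no source says what a number stands for. A block on these numbers was foreseen before the data were examined, and whether the numbers pair the arrays was checked on the data in the same run that gave the calls of both fits. Deviations from the group means correlated across genes at 0.71, 0.57, 0.39 and 0.30 for numbers 1, 2, 3 and 4, and at -0.53 to 0.30 for arrays of different numbers. Every same-numbered pair was above 0.1, so the numbers were taken to pair the arrays, and the fit with the replicate number as a block (the paired fit, 1667 genes) is given beside the planned fit. The pairing comes from the data and not from a stated design. For numbers 3 and 4 it is not distinct, since control 3 correlated at 0.30 with Nf1Prx1 4 and control 4 at 0.29 with Nf1Prx1 3, and the arrays of numbers 2 and 3 differ in sex-linked transcripts. The limit of 0.1 did not single out the numbered pairs, since the crossed correlations of numbers 3 and 4 exceeded it too. The block was kept on the deviations whose spread it then removes, so adjusted p values of the paired fit may be too small.

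The fits were tested on simulated data with 100 changed genes of each size among 19938. With arrays simulated as independent, changes of 0.5 and 1 on the log2 scale were recovered for 28 and 77 genes without the block and for 1 and 41 with it, at 5 and 0 false calls. With arrays simulated as pairs, 27 and 73 were recovered without the block and 25 and 76 with it, at 3 and 2 false calls. In these simulations genes varied independently and all arrays had the same spread, while weights of the real arrays ran from 0.265 to 4.42. The false call counts therefore do not carry over to the fits of the real arrays. A shift of 0.3 in 5 lists was recovered in 5 by camera with the preset correlation, with 1 false call in 32 unshifted lists, and in 3 with the estimated correlation, with 0 false calls. Genes were simulated here as independent, while the correlation estimated among the adipocyte genes of the real arrays was 0.82. The simulation therefore cannot tell how many false calls the preset correlation gives in these data.

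Alternatives fixed beforehand were quantile normalization, subtraction of array medians, leaving out dim genes, averaging clusters, testing every cluster, eBayes with trend and robust variance, array weights, a plain test per gene, a test against a 1.2-fold change, the replicate block, leaving out each array, stricter thresholds and lists without shared members. After the data were examined, 7 marker lists for other tissues were written, of pancreatic acinar cells, pancreatic islets and ducts, brown adipocytes, skeletal muscle fibres, hindlimb position, forelimb position and bone marrow precursors, some of their members after their values had been seen. Fits without the arrays that carried such transcripts, with the Ucp1 or Uty level as a covariate, and with the first singular vector of the residuals as a covariate were added then, as were all variants of the paired fit.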

Results

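Triceps muscle of 8 mice aged 3 months was profiled on Affymetrix Mouse Gene 1.0 ST arrays, with 4 wild-type control animals, 4 Nf1Prx1 mutants and 1 array per animal. Nf1Prx1 is a conditional knockout of Nf1 in which a Cre recombinase driven by the Prx1 limb enhancer acts in the mesenchyme of the limb buds. Nf1 encodes neurofibromin, a GTPase-activating protein that turns Ras off. The series title asks what muscle development needs from neurofibromin, and the comparison of mutant with control arrays addresses which transcripts of adult triceps differ in these mutants. Cells in which Cre did not act keep Nf1, so the whole muscle is not taken to lack it. Levels were log2 values for 19938 genes, array medians lay between 7.23 and 7.39, and correlations between arrays ran from 0.928 to 0.994 across genes. The number of arrays limits the precision of every value.

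No change of Nf1 as a whole transcript passed a test, and its mean was slightly lower in Nf1Prx1 triceps. The Nf1 transcript cluster (10379262) had a level of 8.85 ± 0.12 in control and 8.72 ± 0.07 in Nf1Prx1 triceps (SD, n = 4), and the 8 arrays did not part the groups (exact permutation test, two-sided, p = 0.171). The log2 difference was -0.13 (SE 0.09, limma adjusted p = 0.599). The plan took the deletion to remove only part of the gene, so the cluster level need not fall. How much Nf1 RNA came from cells in which Cre acted was not measured, so this level does not tell whether the deletion took place. By probe set, the picture was uneven along the gene. In the authors' deposited table, the 40th of the 58 Nf1 probe sets (10379302) had a mean of 7.3 in control and 5.3 in Nf1Prx1 muscle, 3.97-fold lower, and the adjacent 41st (10379303) went from 9.2 to 8.7, 1.49-fold lower. The groups overlapped for the 40th, at 5.6 to 8.0 in control and 4.5 to 6.2 in Nf1Prx1 muscle. They also did for the 41st, at 8.8 to 9.6 and 8.5 to 8.9. The 39th (10379301) was 1.85-fold higher, at 8.7 against 9.6. Others along the gene were higher too, with the 31st 2.51-fold, the 3rd 1.92-fold, the 33rd 1.65-fold and the 17th 1.26-fold in the authors' deposited table, and these 7 were the probe sets with an unadjusted p under 0.05. The 3rd and the 31st had low and variable control levels, with means of 5.0 (SD 0.65) and 6.0 (SD 0.81). Over all probe sets of the authors' deposited table only the 39th of these 7 passed the threshold, with an adjusted p of 0.0178 computed here, against 0.153 for the 40th, 0.186 for the 41st and 0.234 for the 31st. The 58 probe sets of that deposited table had a median log2 difference of 0.03, with 32 higher and 26 lower. These probe sets were picked after their values were seen, and no genome build or exon map of the probe sets was given in the sources used here, so they were not assigned to exons.

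**Figure D1:**
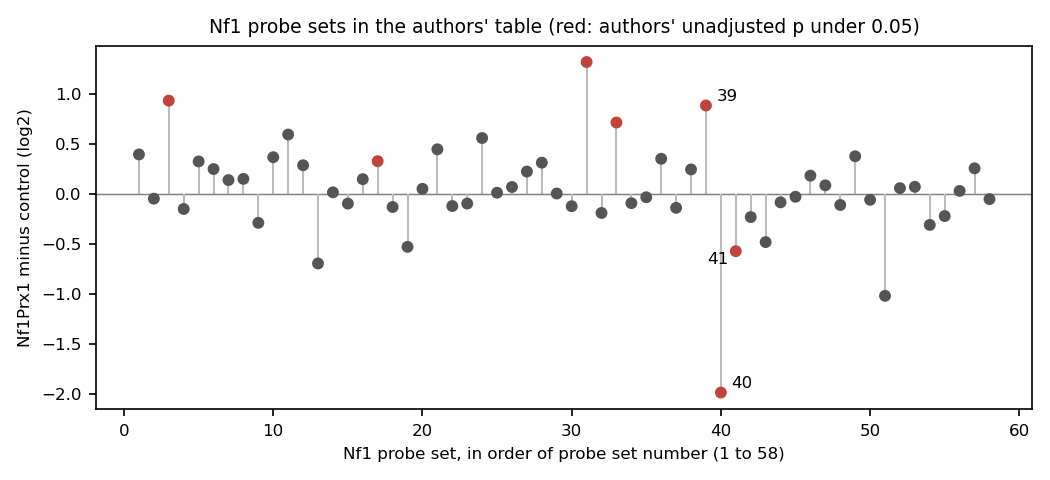
Log2 difference between Nf1Prx1 and control for each of the 58 Nf1 probe sets of the authors' deposited table (vertical axis), in order of probe set number (horizontal axis). Red points had an unadjusted p under 0.05 in that table, and the 40th stands lowest at -1.99 beside the 39th at 0.89.

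On average, Nf1Prx1 triceps held more transcript from adipocyte, lipid synthesis, collagen, basement membrane, fibroblast and macrophage genes, and less from slow-fibre contractile and excitation-contraction coupling genes. Of 37 gene lists fixed before the data were examined, 21 differed between the groups by the camera test with its preset correlation, 14 toward higher and 7 toward lower levels. None of the 37 passed once the correlation among list members was estimated from the arrays, with a lowest adjusted p = 0.397 with an estimated correlation. Gene by gene, the planned limma fit without pairing called 0 of 19938 genes, with a smallest adjusted p of 0.0746, while 2709 genes had an unadjusted p under 0.05 against 996.9 by chance. With the replicate number as a block (the paired fit), 1667 genes passed, 670 higher and 997 lower, and among those at least 1.5-fold apart 390 were higher and 330 lower. That split was not stable, with 777 higher and 705 lower after quantile normalization and more higher than lower genes whenever a pair was left out. Without the arrays numbered 1, 2, 3 or 4 the paired fit called 719 (425 higher, 294 lower), 1202 (688 and 514), 206 (116 and 90) or 50 (38 and 12) genes. From here on, rose and fell are used of single genes only where they passed in the paired fit over all genes, p values of single genes are adjusted values from that fit, and none of these genes passed in the planned unpaired fit. The pairing was read from these same arrays, so the adjusted p values of the paired fit may be too small.

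Adipocyte genes showed the largest median difference of the 37 lists. Of 15 measured members 11 rose, 11 also adjusted over the list alone, and the median member was higher by 1.15 on the log2 scale (camera adjusted p = 8.17e-08; adjusted p = 0.508 with an estimated correlation). Cidec, which coats the lipid droplets of fat cells, rose from 9.28 ± 1.18 to 11.52 ± 0.89 (SD, n = 4), or 4.72-fold (adjusted p = 0.00476). Lipe, the hormone-sensitive lipase, rose 2.22-fold, from 9.73 ± 0.54 to 10.88 ± 0.67 (adjusted p = 0.00780). Of 17 genes for fatty acid and triglyceride synthesis 10 rose, 10 also adjusted over the list alone, with a median difference of 0.70 (camera adjusted p = 0.000357; adjusted p = 0.508 with an estimated correlation). Fasn, the fatty acid synthase, rose 4.25-fold, from 10.17 ± 1.47 to 12.26 ± 0.70 (adjusted p = 0.0158), and the elongase Elovl6 rose 4.22-fold, from 8.50 ± 1.30 to 10.58 ± 1.05 (adjusted p = 0.0228). Both list means were higher in the Nf1Prx1 array of each of the 4 pairs, but the groups overlapped. Control 1, which like Nf1Prx1 1 held Ucp1, Cidea and neutrophil transcripts, had an adipocyte list mean 1.68 above the control average, against 0.40, 0.72 and 1.04 in Nf1Prx1 2, 3 and 4 and 2.65 in Nf1Prx1 1. Without control 1 and Nf1Prx1 1 the median adipocyte difference was 1.16 (camera with the preset correlation, adjusted p = 6.68e-18). That p takes the members as nearly independent, and no estimated correlation was tried without these arrays. Over the 21 alternatives the adipocyte median ran from 0.85 to 1.85. Leaving out the arrays numbered 1, 2, 3 or 4, the paired fit called 10, 11, 7 or 3 adipocyte genes and 10, 9, 1 or 0 lipid synthesis genes.

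Matrix genes were higher on average in Nf1Prx1 triceps, but the groups overlapped. Of 29 measured fibrillar collagens and matrix proteins 10 rose (14 adjusted over the list alone), with a median difference of 0.44 (camera adjusted p = 1.04e-08; adjusted p = 0.508 with an estimated correlation). Col6a3, a chain of the collagen VI around muscle fibres, rose 1.61-fold from a control level of 9.31 ± 0.10 (SD, n = 4; adjusted p = 0.0184), and the proteoglycan biglycan, Bgn, rose 1.77-fold, from 10.88 ± 0.32 to 11.70 ± 0.35 (adjusted p = 0.0139). Of 14 basement membrane genes 6 rose (10 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 9.79e-07; adjusted p = 0.508 with an estimated correlation). The laminin chain Lamb1 rose 1.74-fold, from 8.55 ± 0.25 to 9.35 ± 0.42 (adjusted p = 0.00899), and nidogen 2, Nid2, rose 1.55-fold, from 8.22 ± 0.14 to 8.85 ± 0.28 (adjusted p = 0.0142). Among 23 matrix crosslinking and remodelling enzymes Mmp19, Mmp2, Mmp14, Pcolce and Ctsk rose and the protease Adamts1 fell (8 and 1 adjusted over the list alone), with a list median of 0.23 (camera adjusted p = 0.00280; adjusted p = 0.508 with an estimated correlation). Among 22 genes of fibroblasts and fibro-adipogenic progenitors, the connective tissue cells of muscle, Pdgfra, Mgp and Gsn rose and Prrx1 fell (13 and 2 adjusted over the list alone), with a list median of 0.36 (camera adjusted p = 3.31e-06; adjusted p = 0.508 with an estimated correlation). Pdgfra, the receptor used to sort these progenitors, rose 1.80-fold, from 9.62 ± 0.23 to 10.47 ± 0.36 (adjusted p = 0.0201). Prrx1, the gene whose limb enhancer drives the Prx1 Cre line, was 1.48-fold lower (adjusted p = 0.0252). Relative to the control average, control 1 lay above Nf1Prx1 2 in the list means of collagens (0.38 against -0.06), enzymes (0.21 against -0.19) and fibroblast genes (0.25 against -0.01), and control 4 did in the basement membrane list (0.08 against 0.06). Without control 1, Nf1Prx1 1 and Nf1Prx1 2 the medians were 0.66 for collagens and matrix, 0.47 for basement membrane, 0.35 for enzymes and 0.57 for fibroblasts. Over the 21 alternatives the median ran from 0.29 to 0.66 for collagens and matrix, 0.28 to 0.47 for basement membrane and 0.28 to 0.57 for fibroblasts. The enzyme median ranged from 0.11 without Nf1Prx1 1 to 0.37 without Nf1Prx1 2. With number 1, 2, 3 or 4 left out, the genes called higher by the paired fit were 8, 10, 0 or 0 for collagens and matrix, 5, 7, 1 or 0 for basement membrane, 3, 4, 0 or 0 for enzymes and 7, 4, 2 or 0 for fibroblasts. Calls over all genes also fell most without number 3 or 4, so this loss was not particular to matrix genes.

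Immune cell genes were also higher on average, again with overlap. Of 25 macrophage genes 10 rose (17 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 2.93e-11; adjusted p = 0.508 with an estimated correlation). Cd74, the invariant chain of antigen presentation, rose 2.23-fold, from 10.36 ± 0.47 to 11.52 ± 0.10 (SD, n = 4; adjusted p = 0.0187), and Lgals3, galectin 3, rose 1.83-fold, from 8.33 ± 0.35 to 9.20 ± 0.32 (adjusted p = 0.00780). The macrophage list mean of control 1, one of the arrays with neutrophil transcripts, was 0.56, above Nf1Prx1 2 (0.27) and Nf1Prx1 3 (0.45). The macrophage median was 0.65 without control 1 and Nf1Prx1 1 and 0.78 without Nf1Prx1 2 as well. Among 18 complement, cytokine and chemokine genes Ccl11, C1ra, C1s1 and C4b rose (6 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.000639; adjusted p = 0.397 with an estimated correlation). The median of this list was 0.51 with dim genes left out. Ccl11, which attracts eosinophils, rose 1.72-fold, from 10.65 ± 0.17 to 11.43 ± 0.37 (adjusted p = 0.0126). None of 16 interferon response genes passed (5 adjusted over the list alone), while their median was 0.38 (camera adjusted p = 3.63e-05; adjusted p = 0.508 with an estimated correlation). Nf1Prx1 2 did not share this, with an interferon list mean of -0.17 against 0.08 in control 2. Of 16 lymphocyte genes only the chemokine Ccl5 rose (1 adjusted over the list alone), 2.28-fold (adjusted p = 0.0231), with a list median of 0.28 (camera adjusted p = 1.01e-05; adjusted p = 0.508 with an estimated correlation) and a list mean of 1.07 in Nf1Prx1 1 against 0.05 to 0.18 in the other Nf1Prx1 arrays. The lymphocyte median was 0.13 without control 1 and Nf1Prx1 1 (camera adjusted p = 0.00294) and 0.09 without Nf1Prx1 2 as well (adjusted p = 0.0412). With dim genes left out the call ended (camera adjusted p = 0.0880), although the median was then 0.61. Of 16 mast cell and granulocyte genes only Kit, the stem cell factor receptor, rose (0 adjusted over the list alone), 1.33-fold (adjusted p = 0.0461), with a list median of 0.19 (camera adjusted p = 0.0193; adjusted p = 0.655 with an estimated correlation). This list stood at 1.17 in control 1 and 1.23 in Nf1Prx1 1, the arrays with neutrophil transcripts, against -0.47 to -0.03 in the others. The mast cell and granulocyte call ended without control 2 (camera adjusted p = 0.148), control 3 (0.145), control 4 (0.0639) or Nf1Prx1 1 (0.569, with a median of -0.05). Over the 21 alternatives its median ran from -0.05 to 0.46. With number 1, 2, 3 or 4 left out, the paired fit called 18, 8, 1 or 0 macrophage genes, 5, 2, 0 or 0 complement and chemokine genes, 0, 7, 0 or 0 interferon response genes, 1, 2, 0 or 0 lymphocyte genes and 2, 0, 0 or 0 mast cell and granulocyte genes.

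Contractile and calcium-handling genes of muscle fibres were lower on average in Nf1Prx1 triceps, those of slow fibres most and those of fast fibres least steadily. Of 14 slow-fibre contractile genes 6 fell (10 adjusted over the list alone), with a median of -1.12 (camera adjusted p = 4.93e-05; adjusted p = 0.508 with an estimated correlation). Myl3, the slow myosin essential light chain, was 3.42-fold lower, at 9.95 ± 0.19 in control and 8.17 ± 1.06 in Nf1Prx1 triceps (SD, n = 4; adjusted p = 0.0235), and Ankrd2, a stretch-responsive protein of slow fibres, was 2.76-fold lower, at 10.89 ± 0.42 against 9.42 ± 0.62 (adjusted p = 0.0296). Nf1Prx1 3 did not share this, with a list mean of 0.17 against -1.37 to -1.30 in the other Nf1Prx1 arrays. Of 17 excitation-contraction coupling and calcium-handling genes 7 fell (12 adjusted over the list alone), with a median of -0.48 (camera adjusted p = 0.000361; adjusted p = 0.539 with an estimated correlation). Stac3, which links the surface calcium channel to calcium release, was 1.60-fold lower, at 10.57 ± 0.15 against 9.89 ± 0.44 (adjusted p = 0.0234), and the calcium channel subunit Cacng1 was 1.49-fold lower, at 12.08 ± 0.21 against 11.50 ± 0.33 (adjusted p = 0.0176). The coupling list was lowest in Nf1Prx1 1, at -1.19 against -0.53, -0.18 and -0.04 in the other Nf1Prx1 arrays and -0.35 in control 1, which with Nf1Prx1 1 also had the lowest Ryr1 levels. Its median was -0.19 without control 1, Nf1Prx1 1 and Nf1Prx1 2 (adjusted p = 0.00614), and array weights ended the call (adjusted p = 0.0790). Of 16 fast-fibre contractile genes only Mylk2, the muscle myosin light chain kinase, fell (1 adjusted over the list alone), 1.87-fold, from 12.17 ± 0.22 to 11.27 ± 0.46 (adjusted p = 0.0145), with a list median of -0.20 (camera adjusted p = 0.00103; adjusted p = 0.508 with an estimated correlation). Among 19 satellite cell and myogenic genes the regulators Six4, Mef2c and Myod1 fell and Vcam1, an adhesion molecule that other cells also carry, rose (6 and 2 adjusted over the list alone), with a list median of -0.20 (camera adjusted p = 0.0198; adjusted p = 0.543 with an estimated correlation). The satellite cell call ended without control 3 (median -0.15, camera adjusted p = 0.112), Nf1Prx1 1 (-0.13, 0.128) or Nf1Prx1 2 (-0.18, 0.118). It also ended with dim genes left out (camera adjusted p = 0.228), where the median stayed at -0.20. The fast-fibre median was -0.13 without control 1 and Nf1Prx1 1 (adjusted p = 0.0361). Without Nf1Prx1 2 as well, the fast-fibre median was -0.04 (adjusted p = 0.432) and the satellite cell median -0.12 (adjusted p = 0.528). Without the arrays numbered 1, 2, 3 or 4 the paired fit called 0, 1, 8 or 0 slow-fibre genes and 3, 5, 1 or 0 coupling genes.

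Genes of energy metabolism were lower as lists while few of them passed alone. Of 43 oxidative phosphorylation genes all had a lower mean in Nf1Prx1, and the complex I subunit Ndufa1 and Ndufa4, a subunit of the respiratory chain, fell (2 adjusted over the list alone), with a median of -0.26 (camera adjusted p = 8.75e-07; adjusted p = 0.508 with an estimated correlation). Ndufa4 was 1.54-fold lower, at 11.97 ± 0.24 in control and 11.34 ± 0.36 in Nf1Prx1 triceps (SD, n = 4; adjusted p = 0.0182). Among 21 genes of the tricarboxylic acid cycle and mitochondrial biogenesis the nuclear receptors Esrrb and Esrrg, which regulate mitochondrial genes and are no enzymes of the cycle, fell (4 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 0.000401; adjusted p = 0.539 with an estimated correlation). Among 22 genes of glycolysis and glycogen metabolism hexokinase Hk2 and Ugp2, which makes the sugar donor for glycogen, fell (7 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 0.000437; adjusted p = 0.508 with an estimated correlation). Ugp2 was 1.51-fold lower, at 11.92 ± 0.08 against 11.32 ± 0.35 (adjusted p = 0.0287). Nf1Prx1 2, the array with pancreatic transcripts, had the lowest oxidative phosphorylation mean at -0.62, against -0.27 to -0.03 in the other Nf1Prx1 arrays. Genes above 9 on the log2 scale lay 0.34 lower in that array, in the median, than the mean of the other Nf1Prx1 arrays, so its lower list means need not be particular to energy metabolism. Without control 1, Nf1Prx1 1 and Nf1Prx1 2 the medians of these 3 lists were -0.03, -0.13 and -0.12, with adjusted p of 0.705, 0.240 and 0.0653. With number 1, 2, 3 or 4 left out, the paired fit called 1, 1, 2 or 0 oxidative phosphorylation genes, 0 of the tricarboxylic acid cycle list each time and 0, 1, 0 or 0 glycolysis genes.

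Genes induced by Ras-ERK signalling, the pathway that neurofibromin restrains, were slightly higher on average as a list, but the groups overlapped. Of 19 such genes Spry4 and Etv1 rose (2 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.00210; adjusted p = 0.508 with an estimated correlation). The median was 0.16 without control 1 and Nf1Prx1 1, 0.19 without Nf1Prx1 2 as well and 0.23 with dim genes left out. Relative to the control average, the list mean of control 4 was 0.100, above Nf1Prx1 2 at 0.094. Spry4, a feedback inhibitor of the pathway, rose 1.44-fold, from 7.97 ± 0.24 to 8.50 ± 0.18 (SD, n = 4; adjusted p = 0.0185), and the transcription factor Etv1 rose 1.54-fold, from 8.31 ± 0.24 to 8.94 ± 0.31 (adjusted p = 0.0114). Spry4 overlapped between the groups, with control 4 at 8.301 above Nf1Prx1 2 at 8.288, while Etv1 did not. Among 20 genes of the unfolded protein response the chaperone Pdia4 and Asns, the asparagine synthetase of the amino acid response, rose (2 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.000639; adjusted p = 0.508 with an estimated correlation). Asns rose 3.46-fold, from 8.20 ± 0.78 to 9.99 ± 1.10 (adjusted p = 0.0262). It was highest in Nf1Prx1 2 at 11.31, and control 1 (9.33) lay above Nf1Prx1 3 (8.91) and Nf1Prx1 4 (9.28). This list was highest in Nf1Prx1 2, the array with pancreatic transcripts, at 0.54 against 0.08 to 0.26 in the other Nf1Prx1 arrays, and its median was 0.10 without Nf1Prx1 2 (adjusted p = 0.00943). None of 13 Schwann cell and nerve genes passed (0 adjusted over the list alone), and their median was 0.09 (camera adjusted p = 0.0406; adjusted p = 0.508 with an estimated correlation; 0.0710 in the paired fit). The Schwann cell call ended without control 1 (median 0.08, camera adjusted p = 0.0594), control 3 (0.05, 0.174), Nf1Prx1 3 (0.12, 0.0684) or Nf1Prx1 4 (0.07, 0.118). With number 1, 2, 3 or 4 left out, the paired fit called 1, 2, 0 or 0 Ras-ERK genes and 1, 4, 0 or 0 unfolded protein response genes.

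The other 16 lists were not called. Their camera adjusted p was 0.105 for cell division (0.0116 in the paired fit), 0.150 for developmental myosins and regenerating fibres, 0.150 for the dystrophin-associated complex and sarcolemma repair, 0.189 for cartilage and bone cells, 0.310 for endothelial cells and 0.339 for the circadian clock. It was 0.423 for tenocytes, 0.423 for erythroid cells, 0.504 for TGF-beta and CCN signalling, 0.504 for pericytes and smooth muscle and 0.504 for the neurofibromin and RasGAP family. The remaining values were 0.649 for the atrophy and denervation response, 0.649 for the neuromuscular junction, 0.723 for fatty acid uptake and beta-oxidation, 0.747 for sex-linked genes and 0.969 for immediate early genes. Single members of these lists passed. Dystrophin (Dmd), Dag1 and Dysf fell while the syntrophins Sntb1 and Sntb2 rose (9 and 3 adjusted over the list alone). In the atrophy list the ubiquitin ligase Trim63, Eda2r and Fbxo31 fell and the metallothioneins Mt1 and Mt2 and the transcription factor Runx1 rose (5 and 3 adjusted over the list alone). Trim63 was 1.84-fold lower, at 10.50 ± 0.35 in control and 9.63 ± 0.24 in Nf1Prx1 triceps (SD, n = 4; adjusted p = 0.0237). Fst, which binds activin and myostatin, rose and Ccn1 fell (1 and 2 adjusted over the list alone). Jun and Atf3 fell among immediate early genes, Bhlhe40, Bhlhe41, Cry1 and Tef among clock genes, Chad among tenocyte genes and Alas2 among erythroid genes. Nav1 rose and Rapsn fell at the junction, Angptl4 and Slc27a1 rose and Mlycd fell in fatty acid uptake and oxidation, and Cspg4 rose and Abcc9 fell in the pericyte list. Of the uncalled lists with a camera direction of higher, the neuromuscular junction, fatty acid uptake, immediate early and sex-linked lists had a median below 0. In every list, members named beside a count of 5 or fewer and not covered by the naming rule were named after their values were seen.

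**Figure D2:**
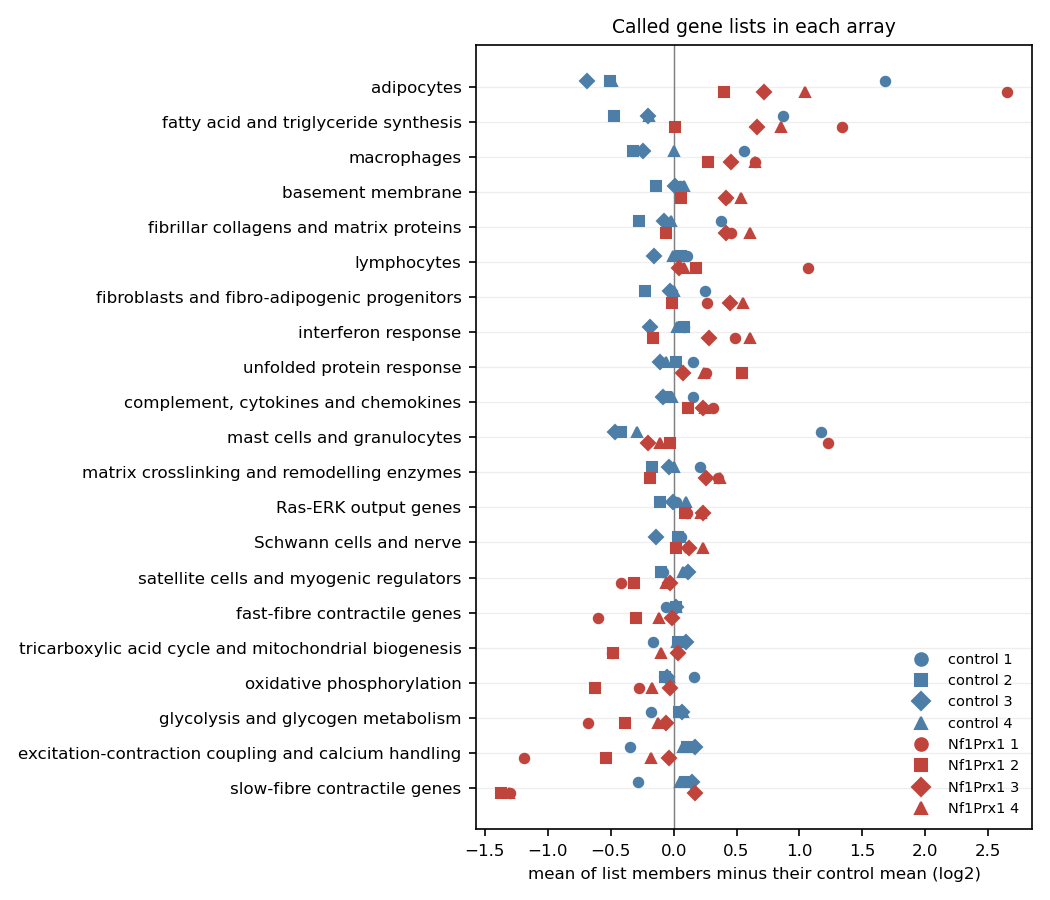
Mean log2 level of the members of each called list in each array, relative to their mean over the 4 control arrays (horizontal axis), with lists ordered by their mean difference between groups (vertical axis). Blue points are control and red points Nf1Prx1 arrays, and point shape gives the replicate number. In the slow-fibre list Nf1Prx1 3 lies at 0.17, apart from the other 3 Nf1Prx1 arrays.

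Among the 10 genes with the smallest p of the unpaired fit in each direction, Cyp2e1, an ethanol-metabolising cytochrome P450, had the largest change. It rose 6.46-fold, from 9.74 ± 0.75 to 12.43 ± 0.65 (SD, n = 4; adjusted p = 0.000429). The related Cyp2f2 rose 5.28-fold, from 8.19 ± 0.26 to 10.59 ± 0.89 (adjusted p = 0.00492). Like the adipocyte list mean, both genes were highest among controls in control 1 (10.71 and 8.50) and among mutants in Nf1Prx1 1 (13.33 and 11.46). Whether their rise comes from fat in or around the muscle was not tested. In no order of size, log2 differences (SE from the unpaired fit) were 0.87 (SE 0.12) for the epidermal growth factor receptor Egfr, 0.85 (SE 0.09) for the BMP-binding protein Bmper, 1.27 (SE 0.20) for Srpx and 0.79 (SE 0.12) for progranulin (Grn). The lysosomal reductase Ifi30 (0.94), Arhgap32 (0.64), Ly6e (0.64) and the inflammasome sensor Naip2 (0.58) completed the higher genes. Tspan8, a tetraspanin, was lowest by log2 difference at -1.45 (SE 0.19), followed by Mettl11b at -1.34 (SE 0.18), Arhgap20 at -1.18 (SE 0.14) and Ppp1r27 at -1.06 (SE 0.17). Pld5 (-0.82), the scaffold protein Homer1 (-0.76), the complex I assembly factor Ndufaf5 (-0.74), the phosphatase Dusp26 (-0.72), Klhl8 (-0.54) and Npepl1 (-0.52) were the other lower genes. All 20 had the 4 Nf1Prx1 arrays entirely above or below the 4 control arrays, as did 1719 genes, or 8.62% against 2.86% by chance. Their adjusted p lay between 0.0746 and 0.121 in the unpaired fit, and all 20 passed in the paired fit. These 20 were picked by their p in the same arrays, which favours full separation and a pass in the paired fit. Without the arrays numbered 1, 2, 3 or 4, 20, 20, 14 or 6 of them passed.

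**Figure D3:**
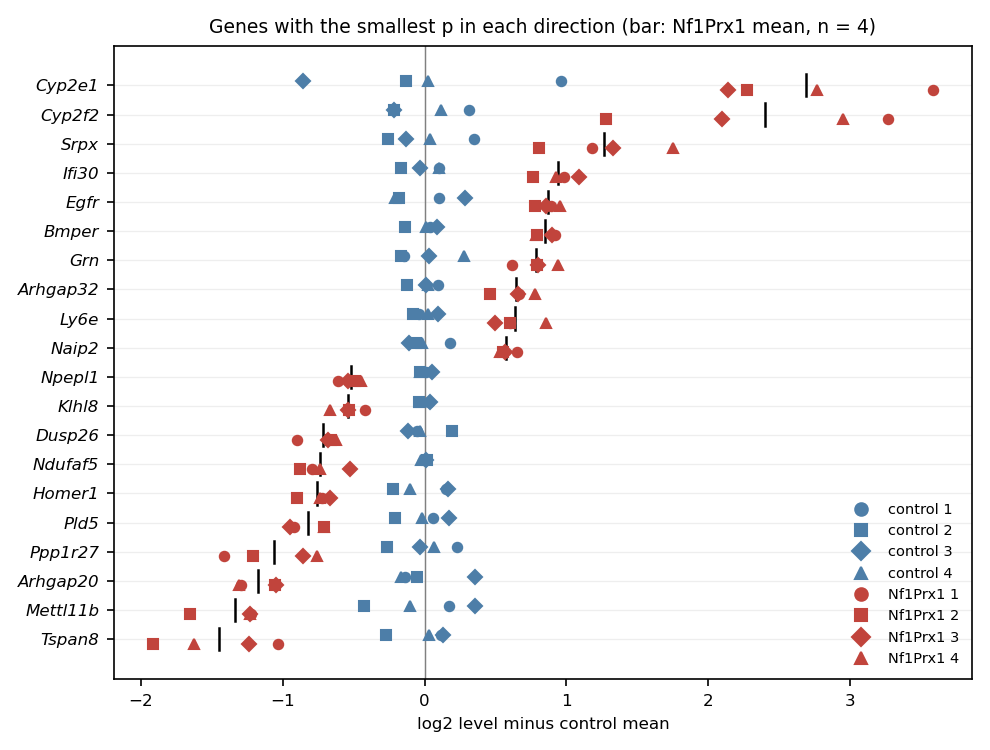
Log2 level of the 10 genes with the smallest p in each direction, one line per gene (vertical axis), in each array relative to the control mean (horizontal axis). Blue points are the 4 control arrays, red points the 4 Nf1Prx1 arrays, point shape gives the replicate number and the black bar the Nf1Prx1 mean. Cyp2e1 stands 2.69 above its control mean and Tspan8 1.45 below.

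The authors also deposited lists of probe sets, about 1 per exon, that were higher or lower in the mutant. Collagen and basement membrane genes were frequent among the higher ones. Per the authors' deposited table, 14 of 31 fibrillar collagen and matrix genes and 10 of 14 basement membrane genes had a probe set in the higher list, where genes with as many probe sets would give 3.93 and 2.64, and none had one in the lower list. By probe set, 8.13% and 9.69% of theirs were in the higher list of the authors' deposited table, against 0.788% of those of all genes. That list also held probe sets of 7 of 25 matrix enzymes (1.36 expected for their number of probe sets), 6 of 23 fibroblast genes (0.861), 4 of 25 macrophage genes (0.983) and 4 of 20 Ras-ERK output genes (0.527). These expected numbers were computed after the counts were seen. It held probe sets of 1 of 17 adipocyte genes, although their median difference there was 1.51. Lrp1, an endocytic receptor, had 39 of its 89 probe sets in the higher list, Col6a3 19 of 47 and Egfr 16 of 33, and Cnksr1, a Ras pathway scaffold, had 13 of its 22 in the lower list of the authors' deposited table. Of the 723 genes of the higher list tested here, 235 rose in the paired fit and 1 fell (24.3 expected if the calls were independent), and of the 528 of the lower list 191 fell and 2 rose (26.4 expected). None of them passed in the unpaired limma fit, where 2709 genes had an unadjusted p under 0.05. Which arrays the authors made the lists from is open, and they may include those used here, so the overlap is a description and not independent evidence. The standard deviations and T values of the deposited table imply 5 arrays per group (4.99 to 5.01), where its notes state 4.

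The arrays did not split by genotype alone. The first 3 principal components held 43.8%, 30% and 11.1% of the variance, and control 1 lay nearer to Nf1Prx1 3 and 4 (correlations across genes of 0.977 and 0.977) than to control 2 (0.964). Digestive enzymes of the pancreas, such as the trypsinogen Prss2, made Nf1Prx1 2 stand apart. The median of 20 acinar cell genes was 13.76 in Nf1Prx1 2, 9.76 in control 2 and 8.07 in Nf1Prx1 3, against 6.75 to 6.95 in the other arrays. All 20 were among the 40 genes that stood highest in Nf1Prx1 2. The list was written after the data were examined, so this overlap is no test. Being outside this acinar list does not set a gene apart from the pancreas. The 40 also held the trypsins Try10 and Prss3 and the islet hormones Gcg and Iapp. Control 1 and Nf1Prx1 1 shared another set. Ucp1, the uncoupling protein of thermogenic fat, was at 10.18 and 9.75 there and at 6.01 to 6.24 elsewhere, the neutrophil granule gene Ngp at 10.98 and 11.57 against 5.45 to 7.06, and Hoxc10 at 10.07 and 9.84 against 6.09 to 6.53. The median of 16 genes of skeletal muscle fibres was 13.12 to 13.53 in all 8 arrays. In Nf1Prx1 2 these fibre genes lay 0.03 below the mean of the other Nf1Prx1 arrays in the median, against 0.34 for genes above 9 on the log2 scale. The fibre median of Nf1Prx1 2 was 13.30, above Nf1Prx1 1 at 13.12 but below Nf1Prx1 3 and 4 at 13.53 and 13.45. The 0.03 therefore does not show that fibre transcripts were undiluted in Nf1Prx1 2. Whether levels this high hide a change in fibre content was not tested. Without control 1, Nf1Prx1 1 and Nf1Prx1 2 the unpaired limma fit called 1215 genes, 890 higher and 325 lower, and 761 of them were also called in the same direction by the paired fit. All 5 arrays of this fit are also in the paired fit, so the overlap is no independent evidence.

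**Figure D4:**
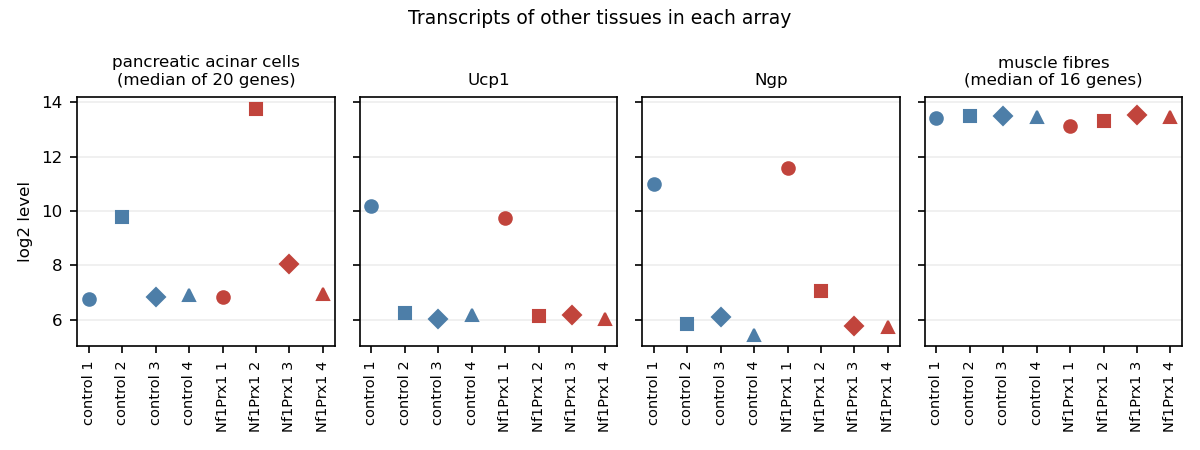
Log2 level in each array (vertical axis) of Ucp1 and Ngp, and the median of pancreatic acinar genes and of muscle fibre genes, in 4 panels with arrays on the horizontal axis. Blue points are control and red points Nf1Prx1 arrays. The acinar median peaks at 13.76 in Nf1Prx1 2 and at 9.76 in control 2, Ucp1 and Ngp in control 1 and Nf1Prx1 1, and the muscle fibre median stays between 13.12 and 13.53.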

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

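Every test of an explanation given here was chosen after the result it concerns had been seen. Within each group of 4 arrays, a value was singled out when its gap to the nearest other array exceeded the critical value of Dixon's test for 4 values at 5%, as a share of the group's range, and 26 of 264 gene and list values met this, where chance gives about 1 in 20. Control 1 was the array apart for 9 of them. It was highest for Scx (gap 0.947 of the range), Comp (0.833), Lipe (0.917), Kit (0.851) and the adipocyte (0.915), mast cell and granulocyte (0.894) and oxidative phosphorylation (0.850) list means, and lowest for the fast-fibre (0.973) and glycolysis (0.865) list means. Nf1Prx1 1 was lowest for Eya1 (0.926) and Cacng1 (0.886) and highest for Gzma (0.854) and for the lymphocyte (0.869), mast cell and granulocyte (0.875) and erythroid (0.830) list means. Control 2 was lowest for Nid2 (0.855), Ccn1 (0.870) and Myl3 (0.984). Nf1Prx1 2 was lowest for Mettl11b (0.985), C1ra (0.883) and the neurofibromin and RasGAP list mean (0.862). Nf1Prx1 3 was highest for Stbd1 (0.934) and for the slow-fibre list mean (0.955). Control 3 was lowest for the Schwann cell list mean (0.857), control 4 highest for the immediate early list mean (0.912) and Nf1Prx1 4 highest for Nav1 (0.887).

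The first pattern weighed is the pancreatic transcripts of Nf1Prx1 2, where Prss2 reached 13.56, Cpa1 14.15 and Ctrb1 14.36. Loss of Nf1 as a cause shared by the mutants is argued against, since the median acinar level of Nf1Prx1 1, 3 and 4 (SD 0.67) lay 0.0741 above that of the controls while Nf1Prx1 2 lay 6.88 above, and the wild-type control 2 was at 9.76. Pancreas RNA in the sample is a candidate explanation, since 15 of 15 islet, duct and acinar regulator genes not used to find the pattern were highest in Nf1Prx1 2, with Ins2 at 10.19. Chance gives up to 4 for genes that vary independently, which genes of 1 organ need not do. By its summary values, the authors' deposited table does not show this array's acinar levels. Over the acinar probe sets of that table, the highest mutant value had a median of 7.9 and the highest control value a median of 9.4. The difference between these medians was -1.50. How pancreas RNA could have reached a triceps sample was not tested.

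The next is the set of transcripts shared by control 1 and Nf1Prx1 1. Loss of Nf1 does not account for Ucp1 and Cidea, whose mean was 0.15 higher in control 1 than in Nf1Prx1 1. Classical brown fat was not borne out by its other markers but stays open. Of 9 brown adipocyte genes not used to find the pattern, 1 had these arrays as its highest pair. In the other arrays 6 of the 9 lay at or below the median gene level and 2 in the upper quartile. A low level there need not hide brown fat, since the mean of Ucp1 and Cidea was at most 6.24 there, against 10.22 in control 1 and 10.07 in Nf1Prx1 1. How far a small share of brown fat would raise the 9 genes is not known, so the test cannot exclude it. Bone marrow cells may have contributed the neutrophil part, since 10 of 13 granulocyte and erythroid precursor genes not used to find it had these arrays as the highest pair. Chance gives up to 2 for genes that vary independently, which genes of related cells need not do. Of these genes Elane was at 8.64 and 9.64 against 7.17 to 7.80 and Camp at 8.68 and 8.91 against 7.06 to 7.64. Camp also belongs to the fixed mast cell and granulocyte list, in which these arrays stood out. The source of Ucp1, Cidea and the Hoxc genes stays open.

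The last is the higher level of adipocyte genes in Nf1Prx1 triceps. The arrays with Ucp1 and neutrophil transcripts do not account for it, since the median difference without them was 1.16 and 8 of 15 adipocyte genes then passed in the unpaired limma fit. A lower share of muscle fibres as the whole cause is argued against, because it would raise other cell types alike, and the lower quartile of adipocyte genes lay 0.56 above the upper quartiles of endothelial and pericyte genes. White fat carried along at dissection cannot be told apart from fat within the muscle with these arrays, and 1 of 4 control arrays, control 1, lay above the lowest Nf1Prx1 array. Under the candidate explanations left, fat inside the muscle of the mutants and fat around it, the same genes would be higher.

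Other groupings of the 8 arrays were tried against each count. For genes past the adjusted threshold the real split gave 0 and the highest other split 4, and that all 35 splits gave at least as many follows from the 0 and says nothing about chance. For genes with an unadjusted p under 0.05, 3 of 35 splits gave as many as the real 2709, with 3730 as the highest other, so chance is not excluded. Both splits with more, at 3009 and 3730, kept control 1 together with Nf1Prx1 1, the arrays that share Ucp1 and neutrophil transcripts. Among the 8 splits that part all 4 numbered pairs, as the real one does, the highest other count was 408. For gene lists called by camera, 7 of 35 splits gave as many as the real 21, with 27 as the highest other, and 20 was the highest other among the splits that part all pairs, so chance is not excluded. For the paired fit the 8 swaps within pairs are too few for a share under 0.05, with 1667 genes in the real grouping and 0 as the highest other.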

How the results depend on the processing

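Alternatives that left out 2 or 3 arrays, used the Ucp1 or Uty level or the first singular vector of the residuals as a covariate, or varied the paired fit were chosen after seeing the data, and the others were planned. The planned count of 0 genes (limma, adjusted p under 0.05, with 2709 at an unadjusted p under 0.05) became 1667 with the replicate number as a block, 3070 with array weights (1424 higher, 1646 lower), 2 with quantile normalization (Bmper and Ifi30), 1087 with the singular vector and 1058 with the Ucp1 level. It became 96 without control 1 and Nf1Prx1 1 and 1215 without Nf1Prx1 2 as well, and leaving out each array in turn gave 0 to 3, the 3 without Nf1Prx1 3 (Myl2, Myl3 and Tnnc1). It stayed at 0 with subtracted array medians, dim genes left out, averaged clusters, every cluster, trend and robust variance, the plain test, the 1.2-fold test and the Uty level. The 2709 genes with unadjusted p under 0.05 became 6645 with array weights, 616 against 1.2-fold, 5038 with the block, 4574 with the singular vector, 4268 without the 3 arrays and 4337 with the Ucp1 level. The paired count of 1667 (670 higher, 997 lower) became 130 at an adjusted p under 0.01 (98 and 32), 720 at 1.5-fold or more (390 and 330), 1482 with quantile normalization (777 and 705), 1835 with array medians subtracted (648 and 1187) and 1794 with dim genes left out (647 and 1147), and ranged from 50 without number 4 to 1202 without number 2, with more higher than lower genes in each fit without a pair. All genes it called kept their direction in each of these fits without a pair. These fits share pairs with the fit that selected the genes, so the kept direction is no independent evidence. The 21 called lists became 0 with an estimated correlation, 0 by fry for 1 direction and 0 by fry for change in either direction, and 18 to 23 under the other 21 alternatives. The paired list test ended the Schwann cell call and added cell division, and it changed no other list call. Of the 21 called lists 12 passed in all 21 alternatives. Array weights ended 6 calls, of fast-fibre, satellite cell, coupling and the 3 energy lists. The Nf1 cluster stayed at -0.18 to -0.05 and did not pass in any of 23 alternatives, while the median of the probe sets in the authors' table was 0.0254 for Nf1. The direction of the listed probe sets was the same in 92.8% by ID and 92.5% by symbol. Counted by gene, it was the same in 87.1% of the higher and 86.6% of the lower list. The lists may come from the arrays used here, so these shares are no independent evidence. Of 2148 values for 94 other named genes under 23 alternatives, 2137 kept their sign, 308 passed and 0 passed with the opposite sign. These genes were chosen by their p in the main fit of the same arrays, which favours a kept sign. The cause of these shifts was not tested. The planned surrogate variable from sva was not run, the authors' other table held no values per array to fit, and the plain and 1.2-fold tests give no list test. Genes near background limit what can be seen, and the arrays give no detection call here.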

Other observations

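The values in this part were singled out after they were seen. Of the 670 genes called higher in the paired fit, 4 outside the fixed lists are given as examples, and no shared function was tested. Car5b, a mitochondrial carbonic anhydrase, was higher by 2.35 on the log2 scale (SE 0.17, limma adjusted p = 0.00355), the retinol carrier Rbp4 by 2.03 (SE 0.30, adjusted p = 0.0151), Pde3b, the phosphodiesterase that insulin activates in fat cells, by 2.01 (SE 0.14, adjusted p = 0.00355) and transferrin, Trf, by 1.78 (SE 0.09, adjusted p = 0.00135). Of these Trf had all 4 Nf1Prx1 arrays above all 4 control arrays. In the authors' deposited table Trf had 16 of 17 probe sets in the higher list, with a median difference of 1.85, and Mup1, a major urinary protein, had 16 of 47 with a median of 1.92.

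Of the genes that fell 4 are given in the same way. Chac1, which degrades glutathione, was lower by 2.09 on the log2 scale in the paired fit (log2 difference -2.09, SE 0.31, limma adjusted p = 0.0150), the muscle protein Mss51 was at -1.55 (SE 0.35, adjusted p = 0.0409), the sarcomere-associated Xirp1 at -1.11 (SE 0.12, adjusted p = 0.00788) and Tbc1d1, which controls glucose transporter traffic in muscle, at -1.12 (SE 0.13, adjusted p = 0.00890). These 4 had all Nf1Prx1 arrays below all control arrays. In the authors' deposited table Chac1 had 3 of its 4 probe sets in the lower list, with a median difference of -1.87. The lysine methyltransferase Smyd2 had 8 of its 13 there, with a median of -1.06.

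The sexes were mixed in both groups. Uty, a gene of the Y chromosome, was at 9.02 and 9.15 in control 1 and 3 and at 9.18 and 7.97 in Nf1Prx1 1 and 2, against 4.86 to 5.15 in the other arrays. Xist, the transcript of the inactive X chromosome, was at 10.54 and 10.85 in control 2 and 4 and at 10.94 and 11.35 in Nf1Prx1 3 and 4. Each group thus held 2 arrays of each kind.

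Single genes set control 1 and Nf1Prx1 1 apart without a test. Ttn was at 12.29 and 12.05 there against 13.15 to 13.54 in the other arrays, and Ryr1 at 12.08 and 11.16 against 12.47 to 12.77. The hindlimb factor Tbx4 was at 7.53 and 7.40 in these arrays against 8.01 to 8.46 in the others, and Hoxc8 at 8.43 and 9.11 against 6.17 to 6.58.

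The marker lists written for other tissues are given by the median of the members that had not been seen before the lists were written. For 9 brown adipocyte genes it was 7.48 and 7.41 in control 1 and Nf1Prx1 1, within the range of 7.21 to 7.60 in the other arrays. For the 4 hindlimb genes Tbx4, Pitx1, Hoxc11 and Hoxc12, with Hoxc8, Hoxc9 and Hoxc10 left aside, it was 7.11 and 6.88 against 6.82 to 7.15, although Tbx4 alone was lowest in these arrays. For 13 bone marrow precursor genes it was 7.49 and 7.62 there against 6.87 to 7.33. The 3 forelimb genes had a median of 7.28 and 7.34 there against 6.64 to 7.0, with Hoxc5 at 7.28 and 8.09 and the forelimb factor Tbx5 at 7.54 and 7.34 against 7.22 to 8.40. The 15 genes of pancreatic islets, ducts and acinar regulators had a median of 7.83 in Nf1Prx1 2 and of 6.67 to 7.02 in the other arrays.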
